A study of Homo sapiens with 6 samples.

How the data were processed

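RNA was sequenced from 6 cultures or aliquots of HCT116, an established human colorectal carcinoma cell line, in 3 groups of 2 libraries: untreated cells, cells given SP2509 at 3 uM for 48 h, and cells in which PIR was knocked down with small interfering RNA (siPIR). Per the labels' protocols, the libraries were made with a directional kit from total RNA. How ribosomal RNA was excluded is not given in the sources used here. Groups were taken from the sample titles. The treatment label of the siPIR samples names SP2509 while their titles name the knockdown alone, so whether these cells also received the compound is open, and no dose was assigned to them. The treatment protocol also names a DMSO arm, and the labels do not say whether the untreated cells received that solvent. A number between 10 and 12 in the sample descriptions is not explained by the labels. Nothing in the labels says that the replicates came from separate cultures, so every p-value measures only the spread between these samples, which may be technical.

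The authors deposited 1 table of estimated counts for 60675 Ensembl genes, in which many values are not whole numbers. FastQC 0.11.8, Trimmomatic 0.32, HISAT2, featureCounts, Subread 1.6.2 and edgeR 3.26.4 are named per the submitters' processing notes, with GRCh38 as the genome build. The annotation release, the strand setting and the rule that produced fractional counts are not given in the sources used here. Shared reads appear to have been divided between features, so the values of near-identical genes, pseudogenes and overlapping genes are uncertain. The deposited counts were rounded to whole numbers for all tests. They summed to between 22622441 and 28816590 per library. A count of 0 allows up to 3 counts in a library, which is between 0.104 and 0.133 CPM (counts divided by the library total on the usual scale) before TMM scaling. Such floors, and the exact intervals given for ratios of counts, cover counting error only.

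Coordinates, biotypes, transcript lengths and GC contents were taken from GENCODE release 29 on GRCh38, in which 57055 of the 60675 Ensembl identifiers were found. GC content and length are those of the longest transcript of a gene. Of the 16503 genes tested, 158 had no GC value.

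Genes were filtered by filterByExpr and scaled by the trimmed mean of M values (TMM), and all 6 libraries were fitted with edgeR 4.0.16 (R 4.3.3) as 3 groups without covariates, by the robust quasi-likelihood test, which left 3 residual degrees of freedom before moderation. Adjusted p-values are by Benjamini and Hochberg over all genes tested, with a threshold of 0.05. Standard errors (SE) of log2 fold changes were obtained from the fold change and its F statistic. CPM values are TMM-scaled unless stated otherwise, and are given as mean ± SD over 2 libraries. Each of 33 gene lists was written before the data were examined, as were the test and the alternatives to it that are named further down as fixed in advance. Of 693 list entries, 692 matched a row of the table, and 32 lists had at least 3 tested members. The lists were tested with camera (limma 3.58.1) with a preset inter-gene correlation of 0.01, and again with an estimated correlation. The second form takes its p-values from the 3 residual degrees of freedom, so it has little power here whatever the correlation. Fry was also run, and its result shows only whether the members of a list moved, without comparing them with other genes.

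The genes named in the text follow a rule fixed with the design. PIR, TERT and KDM1A are always named. In each comparison the 8 largest rises and the 8 largest falls are named (5 and 5 for siPIR against SP2509) among genes past the threshold with an average log2 CPM of at least 3, a symbol, a protein-coding biotype where one is annotated, and no overlap between the groups. From each called list, or list with a large share of members past the threshold, up to 3 members with the smallest adjusted p in the majority direction are named, in the order of the camera p-values, for the first 8 lists (the first 5 in both comparisons of siPIR). Some genes that the rule names are not reported here. Genes named outside this rule are identified as chosen after their values were seen.

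The alternatives fixed in advance were 3 other scalings, DESeq2 1.42.0, limma-voom, no count filter, a filter of 1 CPM in 2 samples, a fit of only the 4 samples compared, a replicate block, a block for the unexplained number, a test against a log2 fold change of 1, a fit that is not robust, the removal of ribosomal protein, mitochondrial and histone genes, and the removal of each library in turn. After the data were seen, a GC-length offset was added. In it the deviation of each library from the mean of all libraries was fitted on GC content and log2 length with natural splines of 5 degrees of freedom each, and the fitted trend was removed in the model. Because the offset is estimated from the same libraries, it also removes any biological change that follows GC content.

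The fits were tested on simulated data with 200 changed genes, as many higher as lower. In the data themselves 68.6% (SP2509) and 86.1% (siPIR) of genes were called against untreated cells. The rates found with few and balanced changes may therefore not carry over to them. For SP2509 against untreated (15760 genes) 96% of 2-fold and 100% of 4-fold changes were recovered, and 7.5% of the calls were false. For siPIR against untreated (15765 genes) the values were 93%, 100% and 4.5%. When a GC-length trend of the fitted size was laid on the siPIR simulation (15951 genes), the fit without an offset made 13390 false calls, 98.7% of all its calls. With the offset it recovered 93% and 98% and made 24 false calls (11.2%), in a simulation whose trend has the form that the offset assumes. Both comparisons with untreated cells use the same 2 control libraries, and their overlap was set beside 100 simulated data sets with no change.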

Results

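Gene expression was measured by RNA sequencing in HCT116 cells, a human colorectal carcinoma line, with 2 libraries from untreated cells, 2 from cells exposed to SP2509 (3 uM, 48 h) and 2 from cells with knockdown of PIR (siPIR, 48 h). The treatment label of the siPIR samples also names SP2509, so whether these cells received the compound as well is open. SP2509 is known as an inhibitor of the histone demethylase LSD1, the product of KDM1A. PIR encodes Pirin, an iron-binding nuclear protein known as a cofactor of NF-kB. The title of the series presents SP2509 as a repressor of TERT, the gene of the catalytic subunit of telomerase, and the comparisons ask how the compound and the loss of Pirin change TERT and the rest of the transcriptome. The untreated libraries held 28816590 and 24945320 counts, the siPIR libraries 24062794 and 22622441, and the SP2509 libraries 26167926 and 27058580. Replicates correlated at 0.991 to 0.996 across the 16503 genes tested. Genes are not independent replicates. The spread between replicates was unequal: the chi-square over genes divided by its degrees of freedom was 20.5 for siPIR, 7.14 for SP2509 and 4.20 for untreated libraries. All groups share an estimate of the spread in the fit. SEs may therefore be too small in comparisons with siPIR and too large for SP2509 against untreated. Untreated and SP2509 libraries correlated at 0.934 to 0.937, and siPIR libraries with all others at 0.749 to 0.791. The first principal component held 83.7% of the variance and set the siPIR libraries apart, and the second held 14% and set SP2509 apart from untreated.

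PIR (ENSG00000087842, chromosome X, 15384799 to 15493564, minus strand) had 519 and 462 counts in untreated libraries, 37 and 39 in siPIR libraries and 377 and 305 in SP2509 libraries. Its level was 14.5 ± 0.18 CPM (SD, n = 2) in untreated cells and 1.98 ± 0.069 CPM in siPIR cells, a log2 fold change of -2.87 (SE 0.175, edgeR adjusted p = 3.39e-09), in the direction that the knockdown label implies. In SP2509 cells PIR was at 13.3 ± 2.1 CPM and did not pass the test (log2 fold change -0.12, SE 0.125, edgeR adjusted p = 0.406). It did pass with upper-quartile scaling (-0.36, edgeR adjusted p = 0.0224) and total counts (-0.51, edgeR adjusted p = 0.00246), and turned to 0.053 without SP2509 replicate 2. TERT (ENSG00000164362, chromosome 5, 1253147 to 1295069, minus strand) had 262 and 223 counts in untreated, 62 and 60 in SP2509, and 3 and 1 in siPIR libraries. In SP2509 cells it fell from 7.15 ± 0.138 to 2.38 ± 0.0761 CPM (log2 fold change -1.58, SE 0.167, edgeR adjusted p = 3.16e-06), to 33.3% of the untreated level with an exact 95% counting interval of 27.1% to 40.7%. The interval does not cover the choice of scaling. By total counts alone the fall was larger, from 9.09 and 8.94 CPM in untreated to 2.37 and 2.22 CPM in SP2509 libraries. In siPIR cells the 4 counts amounted to 1.46% of the untreated level (0.396% to 3.76%), with a log2 fold change of -6.04 (SE 0.329, edgeR adjusted p = 1.14e-09). That value was -6.97 without siPIR replicate 1 and -5.45 without siPIR replicate 2. The longest TERT transcript has a GC content of 65.7%, and transcripts with more than 65% GC had a median log2 fold change of -5.83 in siPIR against untreated libraries. With the GC-length offset, chosen after the data were seen, the TERT change in siPIR cells was -1.65 (edgeR adjusted p = 0.0168) and the PIR change -2.0 (edgeR adjusted p = 1.38e-09). KDM1A (ENSG00000004487, chromosome 1, 23019443 to 23083689, plus strand) fell in SP2509 cells from 194 ± 0.596 to 144 ± 3.45 CPM (log2 fold change -0.43, SE 0.092, edgeR adjusted p = 0.00117). Its change in siPIR cells, -0.22 (SE 0.092, edgeR adjusted p = 0.0395), became a rise of 0.51 with the offset (edgeR adjusted p = 1.27e-06). With the replicate block the fall no longer passed the threshold (edgeR adjusted p = 0.0519), nor with DESeq2 (adjusted p = 0.495), a fit of only the 4 samples compared (0.0667) or the filter of 1 CPM (0.0573). Without untreated replicate 1 or 2, or SP2509 replicate 1 or 2, it no longer passed the threshold (edgeR adjusted p = 0.15, 0.117, 0.0675 and 0.1). TERC, the RNA component of telomerase, had at most 2 counts in any library and was not tested.

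**Figure D1:**
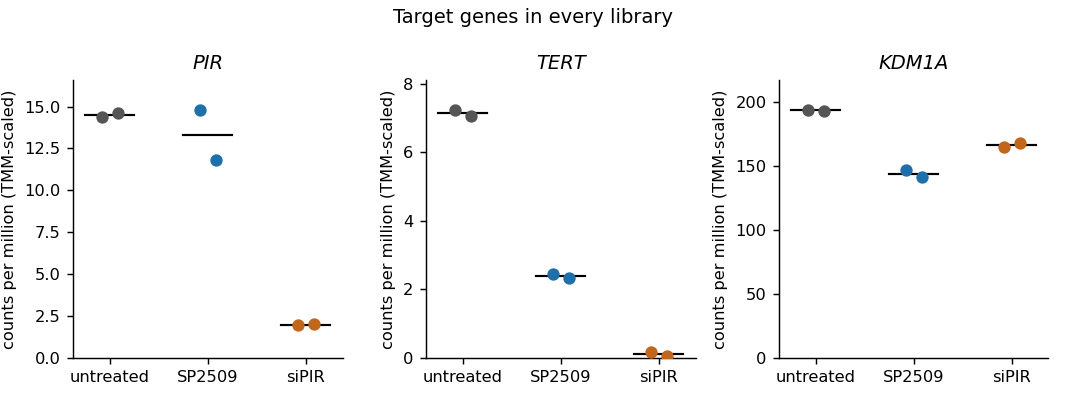
Level of PIR, TERT and KDM1A in CPM (vertical axes, TMM-scaled, from 0) in untreated, SP2509 and siPIR libraries, with a point per library and a line at the mean of 2. TERT lies at 7.15 CPM in untreated and 2.38 CPM in SP2509 cells, and PIR at 14.5 CPM in untreated and 1.98 CPM in siPIR cells.

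In the comparison of SP2509 with untreated cells, the largest rises were in ATF3 and DDIT3, transcription factors of the stress response. ATF3 (chromosome 1, 212565334 to 212620777) rose from 7.08 ± 0.666 to 393 ± 4.64 CPM (log2 fold change 5.79, SE 0.131, edgeR adjusted p = 6.25e-11, n = 2 per group). DDIT3 (chromosome 12, 57516588 to 57521737) rose from 3.31 ± 0.293 to 150 ± 20 CPM, a log2 fold change of 5.50. The keratin genes KRT80 and KRT16 followed with log2 fold changes of 5.45 and 5.33. NRP1, a co-receptor of semaphorins and VEGF, rose by 5.09, the transcription factor gene ETS1 by 4.86, UPP1, which encodes uridine phosphorylase, by 4.85 and CD274, which encodes the immune checkpoint ligand PD-L1, by 4.68. The largest falls were smaller. MFSD3 changed by -3.10, the ion channel gene ASIC1 by -3.08, LONRF2 by -3.06, the imprinted gene PEG10 by -3.03 and RAB26 by -2.97. TMSB15A changed by -2.96, CYP24A1, the vitamin D 24-hydroxylase gene, by -2.82 and NES, the gene of the intermediate filament nestin, by -2.82. All 16 had adjusted p-values of 1.09e-07 or lower by edgeR's quasi-likelihood test, with both libraries of each group on the same side.

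Of 20 tested genes of the endoplasmic reticulum unfolded protein response, 19 rose in SP2509 cells and 0 fell (median log2 fold change 1.14, camera adjusted p = 6.91e-07, and adjusted p = 0.302 with an estimated correlation). Among them were the co-chaperone gene DNAJB9 (3.39), the chaperone gene HSPA5 (3.06) and the transcription factor gene XBP1 (2.83). Of 24 genes of the ATF4 integrated stress response, 20 rose and 1 fell (median 2.04, camera adjusted p = 1.03e-06, and adjusted p = 0.374 with an estimated correlation), with PPP1R15A, a regulator of eIF2alpha dephosphorylation, at 3.65 beside ATF3 and DDIT3. Of 21 immediate early genes, 18 rose and 1 fell (median 1.89, camera adjusted p = 2.32e-06, and adjusted p = 0.302 with an estimated correlation), including the AP-1 genes FOSB (3.93), FOSL1 (3.85) and JUN (3.57). Of 28 p53 target genes, 22 rose and 0 fell (median 0.98, camera adjusted p = 4.59e-06, and adjusted p = 0.302 with an estimated correlation), among them the nuclease gene AEN (2.90), SUSD6 (2.56) and the death receptor gene TNFRSF10A (2.10). Of 21 NF-kB target genes, 14 rose and 3 fell (median 1.16, camera adjusted p = 0.00172, and adjusted p = 0.424 with an estimated correlation), with TNFAIP3, a feedback inhibitor of NF-kB, at 3.42, the chemokine gene CXCL8 at 3.41 and RELB at 1.96. Cytosolic heat shock genes (2 of 16 higher and 8 lower, median -0.33, camera adjusted p = 0.229) and NRF2 targets (11 of 23 higher and 6 lower, median 0.33, camera adjusted p = 0.118) were not called.

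All 26 tested ribosomal protein genes rose in SP2509 cells, by a median log2 fold change of 0.74 (camera adjusted p = 5.28e-06, and adjusted p = 0.503 with an estimated correlation). RPS18 rose by 0.99, RPL30 by 0.92 and RPL11 by 0.80. Of 30 mitosis and G2/M genes, 24 fell and 1 rose (median -0.83, camera adjusted p = 3.45e-05, and adjusted p = 0.414 with an estimated correlation), with the kinesin gene KIF20A at -1.78, HMMR at -1.44 and CCNB1, the cyclin B1 gene, at -1.36. Of 30 DNA replication and S phase genes, 22 fell and 4 rose (median -0.81, camera adjusted p = 0.00129, and adjusted p = 0.424 with an estimated correlation), with the replicative helicase genes MCM6 and MCM3 at -1.83 and -1.60 and the flap endonuclease gene FEN1 at -1.31. Lists called with higher p-values were WNT targets (11 of 15 lower, camera adjusted p = 0.0117), cholesterol biosynthesis (16 of 25 lower, 0.0137), interferon-stimulated genes (14 of 26 lower, 0.0476) and fatty acid synthesis (9 of 11 lower, 0.0476). With an estimated correlation the adjusted p of these 4 lists was 0.414, 0.503, 0.424 and 0.414. Mesenchymal genes (10 of 16 higher, camera adjusted p = 0.0266, and adjusted p = 0.424 with an estimated correlation) and apoptosis regulators (12 of 21 higher, camera adjusted p = 0.0484, and adjusted p = 0.414 with an estimated correlation) completed the 14 called lists. Without untreated replicate 1 the calls of interferon-stimulated genes, fatty acid synthesis and apoptosis regulators were lost (camera adjusted p = 0.059, 0.0631 and 0.059), as they were without SP2509 replicate 2 (0.0787, 0.0576 and 0.0658). Fatty acid synthesis was also lost without SP2509 replicate 1 (0.0729) and apoptosis regulators without untreated replicate 2 (0.054). A block for the number in the sample descriptions ended the calls of mesenchymal genes (0.0556), fatty acid synthesis (0.0572) and apoptosis regulators (0.0556), and the replicate block that of fatty acid synthesis (0.0565). The counts of members were the same when adjusted over the list alone in these 14 lists. The other 18 lists had camera adjusted p-values from 0.0564 to 0.918. Markers of fibroblasts were tested through 4 genes (3 lower, camera adjusted p = 0.17) and markers of leukocytes through 5 (1 higher and 1 lower, 0.918), and endothelial markers had fewer than 3 tested genes.

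**Figure D2:**
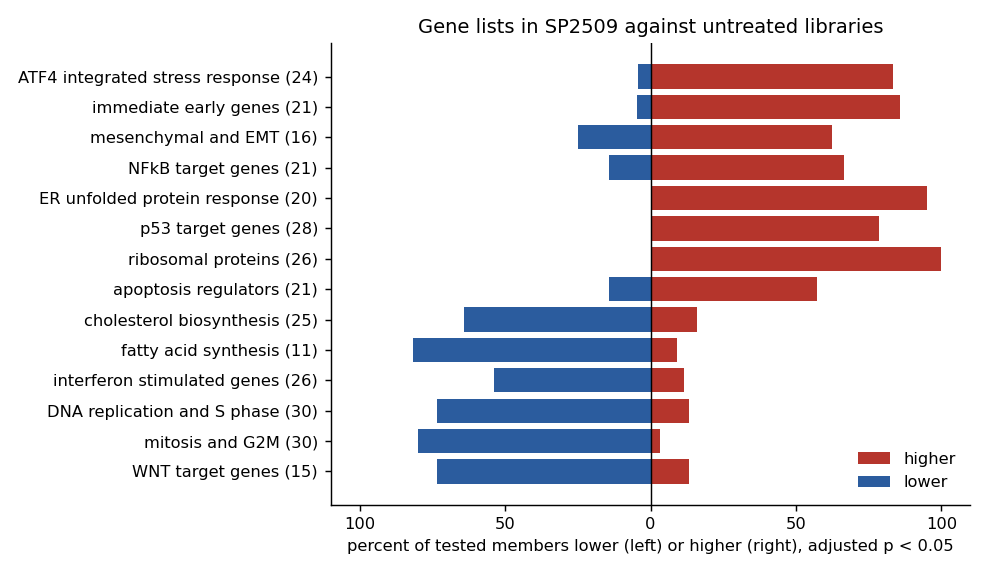
Percent of tested members (horizontal axis, number of tested members in brackets) that were lower (left, blue) or higher (right, red) in SP2509 than in untreated libraries at an edgeR adjusted p below 0.05, for the 14 lists called by camera with a preset correlation. Ribosomal proteins (26 of 26 higher) and the unfolded protein response (19 of 20 higher) had the highest shares of rising members, and 24 of 30 mitosis and G2/M genes were lower. The median of the apoptosis regulators changed sign, to -0.028, with total counts.

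In all, 11316 of 16503 genes differed between SP2509 and untreated cells (5521 higher, 5795 lower), 2125 of the higher and 2952 of the lower by more than 2-fold, and 2960 in a test against a 2-fold change. The split depends on the scaling. The share of calls that were higher was 48.8% with TMM, 36.2% with upper-quartile scaling and 28.3% with total counts alone, as the median log2 fold change of all genes moved from -0.04 to -0.27 and -0.43. The ribosomal protein rise had a median of 0.51 and 0.35 under those scalings, while the median of the apoptosis list turned to -0.028 with total counts. With total counts the median was 0.75 for the unfolded protein response, 0.59 for p53 targets, 0.77 for NF-kB targets, -0.95 for cholesterol biosynthesis, -1.08 for interferon-stimulated genes and -1.02 for fatty acid synthesis. With an estimated correlation 0 of the 32 lists were called by camera (4 at an unadjusted p below 0.05), against 25 by fry. That form of camera has only the 3 residual degrees of freedom, so a lost call does not show that correlation among members explains it. The estimate was 0.866 for ribosomal proteins. For immediate early genes, alone among the called lists, it was below the preset 0.01, at 0.008. Their unadjusted camera p nevertheless went from 2.17e-07 to 0.0132. In the other called lists the estimate ran from 0.014 (apoptosis regulators) to 0.866, so their p-values with the preset assume less correlation than was estimated. Mitochondrial ribosomal RNA took 6.33% and 6.93% of the counts in SP2509 libraries and 1.63% and 1.59% in untreated ones.

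The comparison of siPIR with untreated cells asks what loss of Pirin changes, as far as the labels separate it from the compound. No library is labelled as from cells given a non-targeting siRNA or transfection alone. Effects of transfection or of siRNA in general therefore cannot be told apart from the loss of Pirin in either comparison of siPIR. Fold changes in this comparison followed the GC content of the transcript. The median log2 fold change was 2.39 over the 375 genes with less than 35% GC, 0.06 over the 2900 genes with 45 to 50% GC and -5.83 over the 607 genes with more than 65% GC. The Spearman correlation with GC content across 16345 genes was -0.883, against -0.089 for SP2509 and untreated cells. The mean GC content weighted by counts was 42.1% and 42.6% in the siPIR libraries and between 48.8% and 49.1% in the other 4. Each gene group described for this comparison is given with its median GC content and its value with the GC-length offset. Values of single list members are as fitted unless the offset is named, and so include this trend. Over all 1789 tested genes with 60 to 65% GC, in a list or not, the median log2 fold change was -4.11.

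**Figure D3:**
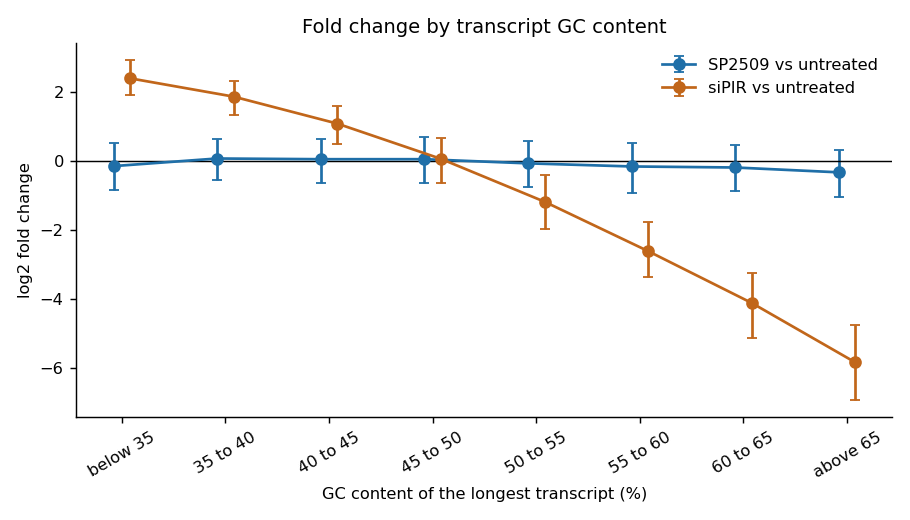
Median log2 fold change (vertical axis, bars from the lower to the upper quartile of genes) against untreated cells by GC content of the longest transcript (horizontal axis, percent) for SP2509 (blue) and siPIR (orange). The siPIR medians run from 2.39 below 35% GC to -5.83 above 65% GC, and the SP2509 medians lie between 0.07 and -0.33.

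The largest rises in siPIR cells were in WNT16, which encodes a secreted WNT ligand (chromosome 7, 121325367 to 121341104), and ARRDC3, an arrestin family gene. WNT16 rose from 30.2 ± 2.09 to 743 ± 54.8 CPM (log2 fold change 4.62, SE 0.12, edgeR adjusted p = 1.18e-11, n = 2 per group), and by 3.47 with the offset. ARRDC3 rose by 4.51 (2.74 with the offset), IL1RAP, a subunit of the interleukin-1 receptor, by 4.26 (3.09), KLHL28 by 4.14 (1.93) and F3, the tissue factor gene, by 4.10 (3.40). The deubiquitinase gene YOD1 rose by 4.03 (2.0), FEM1C by 3.95 (2.23) and SLC2A3, which encodes the glucose transporter GLUT3, by 3.93 (3.64). These 8 transcripts had GC contents between 34.4% and 45.8%. Ranked by fitted fold change, the 8 largest falls were genes with 0 counts in both siPIR libraries, for which only a lower bound against 3 counts per library can be given. These bounds do not fix their rank among the falls. NME3 was at least 228-fold lower, C4orf48 at least 150-fold, SCAND1 at least 147-fold, PRRX2 at least 90.1-fold and ZNF628 at least 61.0-fold. Their GC contents lay between 63.2% and 73.2%. SRXN1, the sulfiredoxin gene, was at least 52.6-fold lower at a GC content of 53.6%, and FP236383.9 and AL592188.11, which have no coordinates in the annotation used, were at least 89.9-fold and 88.7-fold lower.

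Among the lists, ribosomal protein genes came first in siPIR cells (median GC 50.3%), with 22 of 26 lower and 3 higher, a median log2 fold change of -1.75 and a camera adjusted p = 0.0613 (adjusted p = 0.915 with an estimated correlation). RPL8 changed by -4.43, RPLP1 by -4.19 and RPL13 by -3.65. With the offset 21 were lower and 2 higher (median -0.996, camera adjusted p = 0.000103, and adjusted p = 0.794 with an estimated correlation). This list passed the threshold without siPIR replicate 1 (median -1.56, camera adjusted p = 0.0461) and without siPIR replicate 2 (median -1.93, camera adjusted p = 0.0193). Of 30 DNA replication and S phase genes (median GC 49.4%), 19 were lower and 6 higher (median -1.35), among them CDT1 (-5.61), TK1 (-5.45) and MCM2 (-4.19), and with the offset 22 were lower (median -0.88). Of 30 hypoxia and glycolysis genes (median GC 52.8%), 17 were higher and 12 lower (median 0.81, and 0.19 with total counts alone). The collagen prolyl hydroxylase gene P4HA1 rose by 3.90, PDK1, which encodes pyruvate dehydrogenase kinase, by 3.58 and the mitophagy receptor gene BNIP3L by 3.53. With the offset 24 were higher and 2 lower (median 1.92, camera adjusted p = 2.83e-06, and adjusted p = 0.794 with an estimated correlation). Of 26 interferon-stimulated genes (median GC 51.0%), 18 were lower and 5 higher (median -1.64), with ISG15 at -6.70, IFITM3 at -3.83 and OAS3 at -2.51, and with the offset 21 were lower (median -1.15). Of 25 cholesterol biosynthesis genes (median GC 50.5%), 16 were lower and 7 higher (17 and 8 when adjusted over the list alone), with a median of -2.12. MVD, an enzyme gene of the mevalonate pathway, was at -5.74, and with the offset 16 of the list were lower (median -0.70). As fitted these 4 lists were not called (camera adjusted p = 0.347 for S phase and 0.367 for the others, and adjusted p = 0.915 with an estimated correlation). With the offset the adjusted p was 0.000821 for S phase, 0.000849 for interferon-stimulated genes and 0.000726 for cholesterol biosynthesis, and each had an adjusted p = 0.794 with an estimated correlation.

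**Figure D4:**
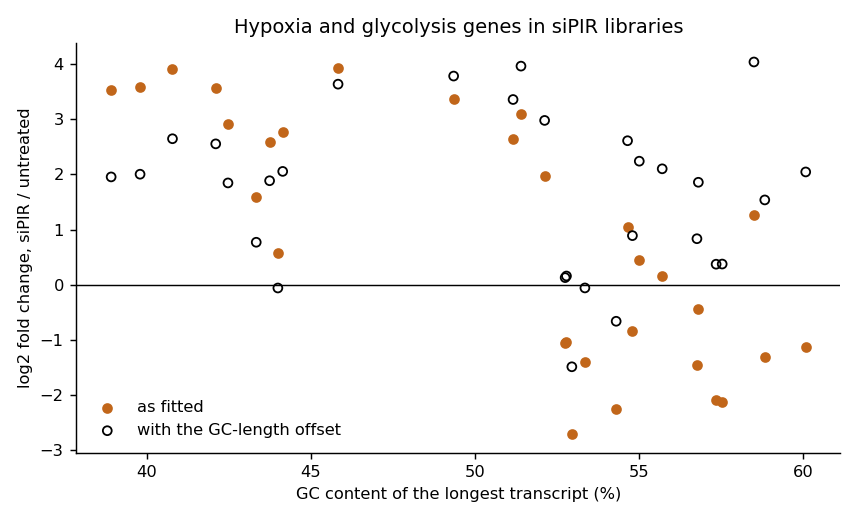
Log2 fold change of siPIR against untreated cells (vertical axis) for the 30 hypoxia and glycolysis genes by GC content of the longest transcript (horizontal axis, percent), as fitted (orange) and with the GC-length offset (open circles). As fitted, 17 genes were higher and 12 lower, and with the offset 24 were higher and 2 lower.

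As fitted, 0 of 32 lists were called by camera in siPIR against untreated cells (3 at an unadjusted p below 0.05, against 29 called by fry), and 10 were called with the offset, 4 of them higher and 6 lower. Among the higher were immediate early genes (GC 55.1%, 16 of 21 higher and 1 lower, median 1.15, camera adjusted p = 0.000726). The p53 targets (GC 50.2%) had 22 of 28 higher and 4 lower (median 0.77, camera adjusted p = 0.00157). The NF-kB targets (GC 53.1%) had 11 of 21 higher and 1 lower (median 0.53, camera adjusted p = 0.0253). As fitted these 3 lists were not called (camera adjusted p = 0.768, 0.7 and 0.671), and 12 NF-kB targets were lower and 6 higher. With an estimated correlation 0 of the 32 lists were called by camera as fitted (0 at an unadjusted p below 0.05), and with the offset the lowest adjusted p was 0.794. In all, 14212 genes differed (6479 higher, 7733 lower), and 10740 with the offset (5397 higher, 5343 lower). The share of calls that were higher was 45.6% with TMM and 33.9% with total counts alone, as the median of all genes moved from -0.28 to -0.89. The offset left a median of -1.26 over the genes with more than 65% GC, so that part of the trend remained among the most GC-rich transcripts, TERT among them.

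The 2 treated groups were also compared with each other. Fold changes followed GC content here too (Spearman correlation -0.837), with a median of -3.98 over genes with 60 to 65% GC. Values of single genes are as fitted unless the offset is named. The largest rises in siPIR relative to SP2509 cells were PLOD2, a collagen lysyl hydroxylase gene (log2 fold change 5.39, SE 0.151, edgeR adjusted p = 7.75e-12, n = 2 per group), and EGLN3, a prolyl hydroxylase gene of the oxygen-sensing pathway (5.31, and 5.65 with the offset). WNT16 (5.20), ARRDC3 (4.63) and ZRANB2 (4.41) followed as fitted, and against untreated cells the offset lowered the rises of WNT16 and ARRDC3. Among these rises the value with the offset in this comparison is reported here for EGLN3 only. How far the other rises follow GC content is therefore left open. Ranked by fitted fold change, the 5 largest falls were genes with 0 counts in siPIR libraries, SRXN1 (at least 179-fold lower), ZNF628 (121-fold), NME3 (109-fold), C4orf48 (93.5-fold) and SCAND1 (86.0-fold). These lower bounds do not fix their rank among the falls. PIR was lower in siPIR than in SP2509 cells (log2 fold change -2.75, SE 0.179, edgeR adjusted p = 6.83e-09, and -1.93 with the offset). TERT was lower as fitted (-4.45, SE 0.414, edgeR adjusted p = 2.76e-07, with -5.39 without siPIR replicate 1 and -3.88 without siPIR replicate 2) and did not differ past the threshold with the offset (-0.37, edgeR adjusted p = 0.65). KDM1A lay close to the threshold (0.21, SE 0.092, edgeR adjusted p = 0.0521). It passed with RLE scaling (0.33, edgeR adjusted p = 0.00648), upper-quartile scaling (0.27, 0.014), DESeq2 (0.33, adjusted p = 0.00262), limma-voom (0.21, 0.0284), the filter of 1 CPM (0.26, 0.0186) and without ribosomal protein, mitochondrial and histone genes (0.21, 0.048). It also passed with the offset (0.84, edgeR adjusted p = 4.67e-10) and without siPIR replicate 1 or 2 (0.23 and 0.20, edgeR adjusted p = 0.0119 and 0.0205), and was at -0.020 with total counts.

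Camera called 5 lists between siPIR and SP2509 cells, with a median GC content of 50.3% for ribosomal proteins, 56.0% for the integrated stress response, 42.9% for mitosis, 55.1% for immediate early genes and 53.1% for NF-kB targets. Of 26 ribosomal protein genes 23 were lower in siPIR cells and 1 higher (camera adjusted p = 0.000295, and adjusted p = 0.925 with an estimated correlation), with RPL8 at -5.07, RPLP1 at -4.83 and RPL13 at -4.42. Of 24 integrated stress response genes 22 were lower and 2 higher (camera adjusted p = 0.000295, and adjusted p = 0.925 with an estimated correlation), including the pseudokinase gene TRIB3 (-6.46), the serine synthesis gene PHGDH (-5.43) and PPP1R15A (-5.24). Of 30 mitosis and G2/M genes 21 were higher and 5 lower (camera adjusted p = 0.014, and adjusted p = 0.925 with an estimated correlation), with HMMR at 3.13, CDK1 at 2.38 and DLGAP5 at 2.24. Immediate early genes (17 of 21 lower, camera adjusted p = 0.0208), with JUNB at -8.03, FOSL1 at -5.83 and IER2 at -4.22, and NF-kB targets (15 of 21 lower, 0.0208), with RELB at -5.23, TNIP1 at -3.64 and TNFAIP2 at -3.53 (-0.15 with the offset, edgeR adjusted p = 0.291), had an adjusted p = 0.925 with an estimated correlation. With the GC-length offset the ribosomal protein and integrated stress response lists passed the threshold (camera adjusted p = 3.1e-07 and 0.000193, and adjusted p = 0.748 for both with an estimated correlation). Mitosis (0.0721), NF-kB targets (0.119) and immediate early genes (0.237) did not. The offset added the unfolded protein response (20 of 20 lower, camera adjusted p = 8.95e-07) and hypoxia and glycolysis (25 of 30 higher and 3 lower, 2.62e-06), which makes 4 lists called, and both had an adjusted p = 0.748 with an estimated correlation. In all, 13920 genes differed between the treated groups (6403 higher in siPIR, 7517 lower), and 11499 with the offset.

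The responses to SP2509 and to siPIR, each against the same untreated libraries, shared 2719 genes that were higher in both, where independent lists would share 2168, and 3389 that were lower in both, where independent lists would share 2715. Opposite calls numbered 2101 genes higher with SP2509 and lower with siPIR (2587 for independent lists) and 1663 the other way (2275). With total counts alone 1318 genes were higher and 5532 lower in both. Across genes the fold changes correlated at r = 0.223 with a covariance of 0.673. In 100 simulations with no change and shared controls, r averaged 0.43, above the observed r, and the covariance averaged 0.0203. The observed covariance exceeded the simulated one by 0.652. With the GC-length offset it did so by 0.479, although the simulated sets were fitted without an offset. In these simulations at most 1 gene per set was called in the same direction in both comparisons. With no gene changed, few shared calls and a small covariance followed from the setting. The simulations therefore give only what noise in the shared controls adds, and do not show that the 2 treatments share a response. The 2 untreated libraries could not be split into separate control pairs, so how far shared controls add to the excess where genes do change was not measured.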

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

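The tests of transcript length, of the share of the top genes, of the knockdown itself, of RNA without poly(A) and of mitochondrial mRNA were chosen after the result was seen, as were the GC-length offset and the mitochondrial genes named here.

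The direct comparison of the treated groups called 5 lists with a preset correlation, and each had an adjusted p = 0.925 with an estimated correlation. The median log2 difference, siPIR minus SP2509, was -2.45 for ribosomal proteins (-1.78 with the offset), -3.69 for the integrated stress response (-3.37 with members at 0 counts set to their bound, and -2.01 with the offset) and 1.24 for mitosis and G2/M (0.35 with the offset). It was -1.52 for immediate early genes (-0.67 with the offset) and -1.42 for NF-kB targets (-0.85 with the offset). With the offset the calls of mitosis, NF-kB targets and immediate early genes were lost (camera adjusted p = 0.0721, 0.119 and 0.237), and ribosomal proteins and the integrated stress response had an adjusted p = 0.748 with an estimated correlation.

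The siPIR libraries were shifted against GC content. Transcript length alone explained 5.2% of the variance of the siPIR fold change against 76.9% for GC content, and the 10 most abundant genes took at most 7.93% of the counts of a siPIR library, below both untreated libraries, which argues against length and against a few dominant genes. A GC-dependent yield of the siPIR libraries predicts the trend within groups of genes that are regulated together, and it was present there: the Spearman correlation with GC content was -0.762 over 26 ribosomal protein genes and -0.861 over 26 nuclear oxidative phosphorylation genes (permutation p = 1e-05 for each, the smallest that 100000 permutations can give, two-sided, and 1e-05 after Benjamini-Hochberg adjustment over the 2 lists). With a Spearman correlation of -0.883 over all 16345 genes, such a trend was likely in groups that span a range of GC contents. The 2 lists therefore restate the trend and do not decide on its cause. A technical cause in RNA quality, amplification or library preparation, which the labels do not record, remains possible. The knockdown itself cannot be told apart from it, because both siPIR libraries carry the shift (count-weighted GC content at most 42.6%) and no other library does.

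Both target genes were lower in siPIR libraries, and the GC trend bears on them differently. TERT lay at percentile 23 among the 200 genes nearest in GC content with a similar untreated level, whose median log2 fold change was -5.08. With the offset TERT kept a log2 fold change of -1.65 (edgeR adjusted p = 0.0168), but genes with more than 65% GC also kept a median of -1.26. The trend alone may therefore account for the fall of TERT, and these libraries show no effect of the knockdown on TERT that can be separated from it. PIR lay at percentile 1 among its own 200 neighbours, outside their 2.5th percentile of -2.68 by about its SE of 0.175, and kept a log2 fold change of -2.0 with the offset, which argues against the GC trend as its whole cause and leaves the knockdown as a hypothesis. In SP2509 cells, where the GC trend was slight, TERT lay at percentile 15.5 of its neighbours, so a fall of its size was not rare among similar genes there.

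Mitochondrial ribosomal RNA took 6.33% and 6.93% of the counts in the SP2509 libraries, against 1.63% and 1.59% in untreated ones, mainly through MT-RNR2 (log2 fold change 2.67), with MT-RNR1 at 0.73. Other RNAs without poly(A) tails had a median log2 fold change of -0.323 (73 genes, 5 higher and 22 lower), which argues only weakly against a weaker removal of such RNA. The set pools histone mRNA, which may have fallen with the S phase genes, and its parts were not separated. The 13 mitochondrial mRNAs had a median of -0.246, which argues against more mitochondrial RNA of every kind, and 11 nuclear rRNA genes a median of -0.042, although 8 of these are copies of the 5.8S gene and the longer nuclear rRNAs were not measured. A step that removes mitochondrial rRNA in particular may have worked less well in these libraries, which stays open beside an effect of the compound.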

How the results depend on the processing

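The GC-length offset, its combination with the replicate block, and, for lists and overlap, some filters were added after the data were seen. Of the named genes, 36 of 41 (SP2509 against untreated), 33 of 34 (siPIR against untreated) and 27 of 28 (siPIR against SP2509) kept direction and side of the threshold under each of the 19 planned settings in which they were tested, where the setting without ribosomal protein, mitochondrial and histone genes leaves out 3 named genes in each comparison. Leaving out each library gave 9340 to 12578, 13550 to 14427 and 13298 to 13959 genes changed, and 11 to 14, 0 to 1 and 5 to 7 lists. Where a library is left out, the lone sample is assumed to vary like the other groups. The test against a 2-fold change gave 2960 genes for SP2509 and, for the overlap, 456 higher and 914 lower in both. With total counts the overlap was 1318 higher and 5532 lower. With an estimated correlation, in the form of camera that has only the 3 residual degrees of freedom, 0 lists were called for SP2509 and 0 between the treated groups, against 14 and 5. Without a count filter 2 lists were called for siPIR against untreated and 10 between the treated groups, and 10 for siPIR against untreated with the offset, alone or with the replicate block. What moved the other counts was not tested. In SP2509 cells upper-quartile scaling and total counts ended the calls of interferon-stimulated genes (camera adjusted p = 0.0803 and 0.124), fatty acid synthesis (0.0619 and 0.0666) and apoptosis regulators (0.0826 and 0.146). A fit of only the 4 samples compared ended those of mesenchymal genes (0.0555) and apoptosis regulators (0.0501), the filter of 1 CPM those of interferon-stimulated genes (0.0527) and apoptosis regulators (0.0673), and the offset that of apoptosis regulators (0.0521). KDM1A in siPIR cells lost its call with RLE scaling (-0.077, edgeR adjusted p = 0.458). The replicate block gave 11179, 14136 and 13816 genes, and same-numbered replicates deviated together at -0.038, -0.024 and 0.081, which gave no reason to pair them.

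Directions were compared between settings for the named genes and for 14 lists (SP2509 against untreated), 10 lists (siPIR against untreated, those called with the offset) and 5 lists (siPIR against SP2509), and among these the following reversed. PIR in SP2509 cells ranged from -0.277 to 0.053 over the left-out libraries, the highest without SP2509 replicate 2. KDM1A in siPIR cells was at 0.51 with the offset, alone or with the block, and at -0.02 against SP2509 with total counts. With total counts the medians of apoptosis regulators (SP2509, -0.028) and, for siPIR, of mitosis (-0.054), mitochondrially encoded genes (-0.49), p53 targets (-0.24) and immediate early genes (-0.44) changed sign. In siPIR cells the offset reversed mitosis (-0.40, and -0.40 with the block), NF-kB targets (0.53, and 0.54 with the block) and mitochondrially encoded genes (-0.55, and -0.55 with the block), upper-quartile scaling reversed mitochondrially encoded genes (-0.047), and a block for the unexplained number immediate early genes (-0.072). Depth limits TERT in siPIR cells, which rests on 4 counts and ranged from -6.97 to -5.45 over the left-out libraries.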

Other observations

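The gene families and single genes in this part were chosen after the values were seen. Of 8 families examined, 3 are not described further. In SP2509 cells these were laminins (4 of 10 higher and 2 lower), integrins (6 of 20 higher and 6 lower) and TNF receptors (8 of 13 higher and 4 lower). No test of a family as a whole is therefore given, only how many of its members passed the edgeR test. Of 20 cytosolic aminoacyl-tRNA synthetase genes, whose products charge tRNAs with amino acids, 14 were higher in SP2509 than in untreated cells and 2 lower (median log2 fold change 0.86). AARS rose by 2.19, GARS by 1.98 and CARS by 1.96, while VARS fell by 0.71. Of 17 mitochondrial synthetase genes 3 were higher and 10 lower. Of 19 keratin genes 13 were higher and 5 lower (median 1.82). KRT15 rose by 3.80 and KRT7 by 2.07, and KRT20 and KRT23 changed by -3.07 and -2.69. KRT19 rose by 1.05 and KRT18 by 0.30, and KRT8 was at -0.05 (edgeR adjusted p = 0.705). Several keratin genes are near-identical in sequence, so their division of reads is uncertain. Of 19 dual-specificity phosphatase genes, feedback inhibitors of MAP kinases among them, 13 were higher and 3 lower, with DUSP5 at 3.96 and DUSP8 at 3.06.

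In siPIR cells 10 of 15 KLF transcription factor genes (median GC 47%) were higher than in untreated cells and 4 lower as fitted, and 10 were higher and 0 lower with the GC-length offset (median 1.15). KLF4 rose by 2.67 as fitted and by 4.46 with the offset. Among the mitochondrial mRNAs in SP2509 cells MT-ND3 fell by 2.10 and MT-ND5 by 1.64, and MT-CO1 was at -0.06 (edgeR adjusted p = 0.643).

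Counts of 0 in both siPIR libraries were found for 34 genes with at least 100 counts in each untreated library, and for 0 genes in the opposite direction. Of the 26 with a GC value, 23 were above 60% GC. SRXN1, at 53.6% GC, was among the exceptions.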
